A study of Homo sapiens with 6 samples.

How the data were processed

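RNA was sequenced from libraries made from total RNA with Illumina TruSeq RNA kits, per the labels, from CT27 trophoblast stem cells with a control shRNA or an shRNA against NOTUM, 3 libraries per group, collected after 8 days of extravillous differentiation. Cells were selected with puromycin after lentiviral delivery, per the series design text, and the replicates were separate transductions per the labels. The shRNA sequences, and so the target site within NOTUM, are not given in the sources used here.

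The authors mapped 100-bp paired reads to the human genome GRCh37 with CLC Genomics Workbench 12.0, per the labels' description field; the submitters' processing notes name the same build. A protocol field of the labels instead names a rat genome, another sequencer model and a comparison of glucose levels; the human gene symbols of the table contradict it, and it was set aside except for the unit. The deposited values are RPKM, reads per kilobase of exon per M mapped reads (M for 1e+06), per the labels and the file headers, with 1 row per transcript and 173113 rows. Filters, the annotation release, strandedness, the treatment of reads that match several genes and whether reads or pairs were counted are not given in the sources used here. The authors' deposited table also holds a p-value and an FDR p-value per transcript from an EDGE test with tagwise dispersions, per the file headers. It holds a signed fold change per transcript, treated as a score: per the file headers it compares the groups, and its values lie at or beyond 1 in size with a negative sign where the NOTUM shRNA is lower. These columns were used only to describe the authors' own comparison.

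RPKM were summed over the transcripts of each of 36479 gene symbols, taken as the row identifiers without their number. All fits used sums of RPKM, not counts, so no count test was run. Genes with a mean of at least 1 RPKM over the 6 libraries were tested, a minimum set after the unit was known and before any gene was tested. The test was limma-trend (limma 3.58.1, R 4.3.3, empirical Bayes with trend and robust settings) on log2(RPKM + 1), NOTUM shRNA minus control shRNA, with Benjamini-Hochberg adjustment and a threshold of 0.05. The design fixed before the data were examined had foreseen counts, with this test as its fallback. Minimums it gave in CPM were read as RPKM. SDs are over the 3 libraries of a group in RPKM, and folds of single genes in the text are ratios of mean RPKM, while counts at a fold of at least 1.5 use the fitted change of log2(RPKM + 1), which leaves out some low genes. The fit was tested on simulated data with the means and spreads of the 12080 genes of this comparison. The 200 genes changed there were drawn only from genes with a mean of at least 5 RPKM. The fit recovered 92% of 100 genes changed 1.5-fold and 99% of 100 genes changed 2-fold, and called 8 of 11880 unchanged genes. Recovery of changes in genes of 1 to 5 RPKM was not measured, since none of those genes was changed. The noise was drawn separately for each gene, so differences of a library shared by many genes were not simulated. The 8 calls do not measure false calls under such differences.

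Depth per library was worked out from the deposited RPKM of genes with 1 transcript, where low values are whole multiples of 1 read. With transcript lengths from the reference annotation, 4578 genes were used and 62.6% to 67.8% of low values came out whole within 1%; why the rest did not was not tested, and whole reads were not recovered for all genes. Depths were 23.5 to 27.6 M in the control group and 27.4 to 33.5 M in the NOTUM shRNA group, with means of 25.4 ± 2.09 and 30.9 ± 3.13 M (SD, n = 3). Coordinates, lengths and GC content came from a GENCODE annotation of GRCh37, the build of the labels, matched by symbol.

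The text names NOTUM; the 12 largest rises and 12 largest falls by log2 fold change among genes past the threshold with a mean of at least 5 RPKM and no overlap between the groups' values, leaving out clone-based names, pseudogenes named after a parent gene XIST and Y-linked genes; a set fixed beforehand (HLA-G, MMP2, ASCL2, ITGA1, MCAM, FLT4, TEAD4, TP63, ITGA6, LRP2, NPPB, PEG3, CGA, SDC1, ERVFRD-1, AXIN2, LGR5, NKD1, RNF43, LEF1 and MKI67); and for each fixed gene list up to 4 members with the smallest adjusted p among those past the threshold. TIMP3, UTRN, EPHB2, EPHB3, TBX3, CCNB1, LIN28B, GATA2, TFAP2A, GDF15, CD74, MT-ND1, LAMB3, LAMA1, COL4A1, OCLN, PSG9, PSG1, HSD17B1, SFRP1, WNT7A, STAT2, EPSTI1, IFIT5, MX1, IFIT2, IFIT3, CRELD2, PDIA4, and the untested LAPTM5, CD14 and VIM were named after their values were seen. The 28 gene lists were also fixed before the data were examined. For each list, members past the threshold were counted in each direction, adjusted over all genes and over the list alone. The 23 lists with at least 5 measured members were tested with camera on log2(RPKM + 1) at a preset correlation of 0.01, adjusted over these lists; 13 passed, and 0 passed with an estimated correlation.

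Alternatives were median-of-ratios scaling, no filter, a mean of at least 5 RPKM, a pseudocount of 0.1, limma without the robust setting, the replicate number as a block, each library left out in turn, an adjusted p of 0.01 and a fold of at least 1.5. The file headers place control replicate 1 on another sequencing lane than the other 5 libraries; with 1 library of 1 group, lane and library cannot be told apart, and the fit without it stands for that check. The planned tests on counts and on unique reads were not run, since the table used holds no counts.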

Results

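RNA was sequenced from CT27 cells, a line of human trophoblast stem cells that can be kept as proliferating progenitors or differentiated into extravillous trophoblast, the invasive cells of the placenta. The cells received a lentiviral shRNA and were collected on day 8 of differentiation. There were 2 groups of 3 libraries each, one with a control shRNA and one with an shRNA against NOTUM, and the replicates were separate transductions per the labels. NOTUM encodes a secreted enzyme that removes the lipid group WNT proteins need to bind their receptors. The values were RPKM per transcript, summed here per gene. The steps between low values gave depths of 23.5, 25.1 and 27.6 M for control replicates 1, 2 and 3, and of 27.4, 31.7 and 33.5 M for NOTUM shRNA replicates 1, 2 and 3. Whether these are reads or read pairs is not stated. A single read on a 1 kb transcript was worth 0.0298 to 0.0426 RPKM. The comparison asks what loss of NOTUM does to gene expression during extravillous differentiation.

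NOTUM itself was 23.6-fold lower in the cells with its shRNA. It lies on chromosome 17 of GRCh37, minus strand, from 79910383 to 79919716, and is annotated as protein coding. Its level was 796, 741 and 723 RPKM in control replicates 1, 2 and 3, and 37.8, 28.7 and 29.1 RPKM in NOTUM shRNA replicates 1, 2 and 3. The mean was 754 ± 37.9 RPKM (SD, n = 3) with the control shRNA and 31.9 ± 5.14 RPKM (SD, n = 3) with the NOTUM shRNA, a log2 fold change of -4.53 (SE 0.09, limma adjusted p = 1.81e-09). The NOTUM shRNA libraries held 4.23% ± 0.683 (SD, n = 3) of the control mean.

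**Figure D1:**
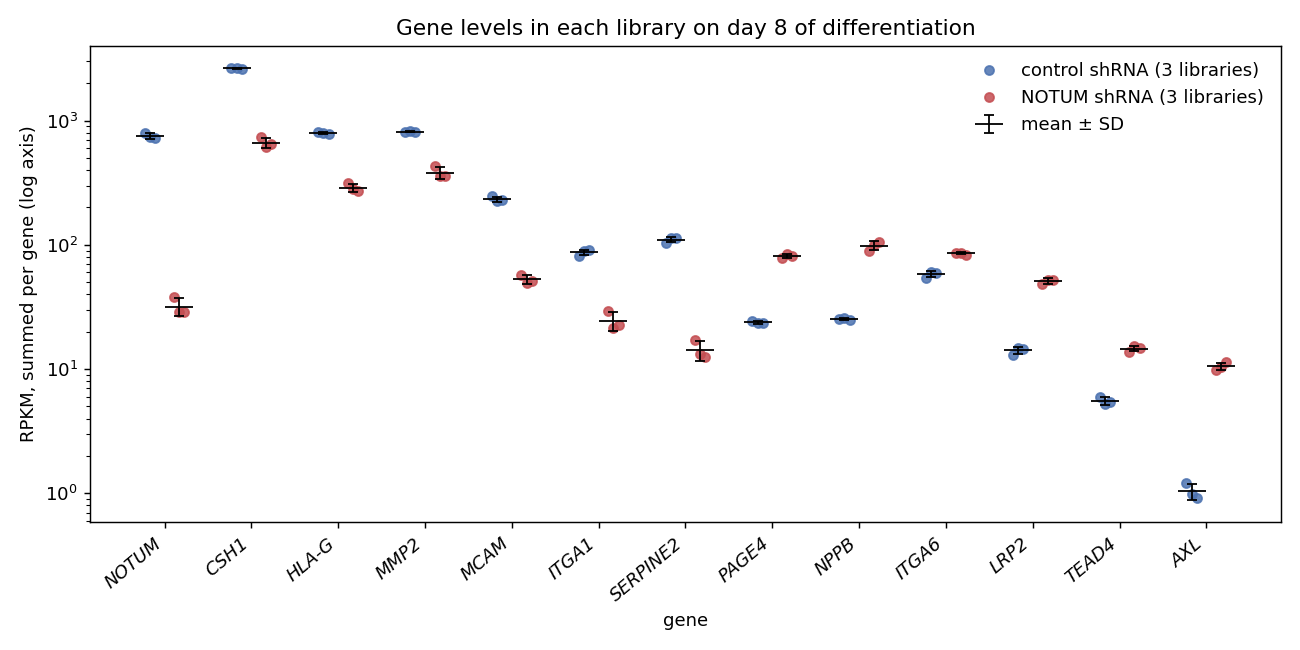
RPKM summed per gene (log axis) for 13 genes in each of the 6 libraries, control shRNA in blue and NOTUM shRNA in red, with black bars for the mean ± SD of 3 libraries and replicates 1, 2 and 3 from left to right within a group. NOTUM lay between 723 and 796 RPKM with the control shRNA and between 28.7 and 37.8 with the NOTUM shRNA; the other genes that fell are CSH1, HLA-G, MMP2, MCAM, ITGA1 and SERPINE2, and the genes that rose are PAGE4, NPPB, ITGA6, LRP2, TEAD4 and AXL.

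With NOTUM reduced, 37 of 47 measured markers of extravillous trophoblast fell and 26 of 33 markers of progenitor trophoblast rose. Camera placed both lists apart from other genes at a preset correlation (adjusted p = 0.107 and adjusted p = 0.15 with an estimated correlation). After NOTUM, the largest falls among genes of at least 5 RPKM were those of SERPINE2, a secreted inhibitor of serine proteases (110 ± 5.47 to 14.3 ± 2.60 RPKM, SD, n = 3), PLXDC2, PIPOX and PAPPA, a secreted protease that cleaves IGF-binding proteins (13.6 ± 0.819 to 1.68 ± 0.340 RPKM). PDE6H, HPGD, CPM, MCAM, GNG4, FAT2 and CSH1 followed, with log2 fold changes from -2.44 to -1.99. The largest rises were those of AXL, a receptor tyrosine kinase (1.04 ± 0.160 to 10.6 ± 0.723 RPKM), and FABP7, a fatty acid binding protein (24.4 ± 2.38 to 142 ± 4.39 RPKM, 5.82-fold). LAMP3, S100A16, GJA1, KRT17, TUBB2B, SLC18A3, MIR205HG, NPPB, PRSS12 and F3 followed, with log2 fold changes from 2.19 to 1.90. Fold changes are on the scale of log2(RPKM + 1), which understates changes of low genes: the ratio of mean RPKM was 10.2 for AXL and 8.07 in the other direction for PAPPA. Of 12080 genes tested with limma, 6666 passed an adjusted p of 0.05, with 4775 higher and 1891 lower under the NOTUM shRNA, and 1666 of them changed at least 1.5-fold on the log2(RPKM + 1) scale. The direction split depends on the scaling of the libraries. Median-of-ratios scaling, which moved the groups by 0.115 on the log2 scale relative to each other, gave 3275 genes higher and 3013 lower. The median log2 fold change of all tested genes was 0.11 in the values as deposited, so list medians are given beside it. Of the genes past the threshold under both scalings, 5166 had the same direction and 0 the opposite one. The scalings differ by nearly the same small shift for every gene, which left little room for opposite calls. The 0 therefore says little about how firm the directions are. The labels give the shRNA of each library with its replicate number and without a sequence. Whether more than 1 shRNA against NOTUM was used is not stated, so effects of reduced NOTUM and off-target effects of the shRNA are not separable here.

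**Figure D2:**
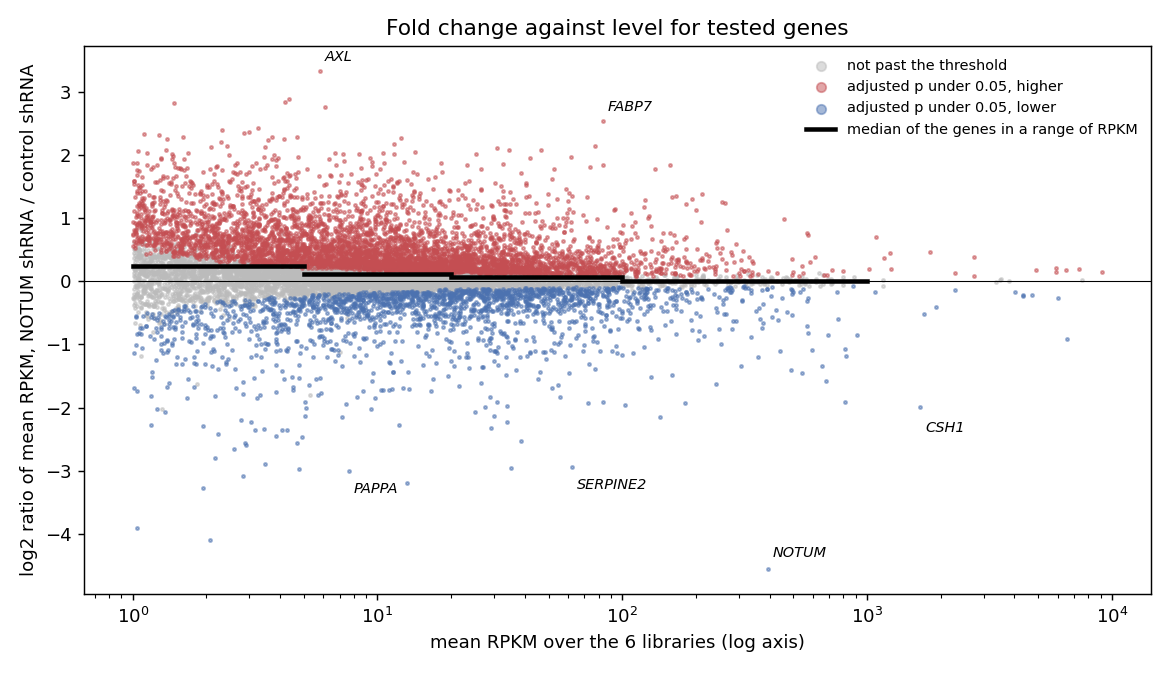
Log2 ratio of mean RPKM, NOTUM shRNA over control shRNA, against the mean RPKM over the 6 libraries (log axis) for the tested genes, colored by direction where the limma adjusted p is under 0.05. Black lines mark the median of the genes in 4 ranges of RPKM, which was 0.23 from 1 to 5 RPKM and 0.01 from 100 to 1000 RPKM.

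Of 47 measured markers of extravillous trophoblast, 37 fell, 6 rose and 4 did not pass; the counts adjusted over the list alone were also 37 and 6. MCAM, an adhesion molecule of invasive trophoblast, was 4.43-fold lower (234 ± 10.7 to 52.7 ± 4.17 RPKM, SD, n = 3). The integrin ITGA1 was 3.56-fold lower and HLA-G, the nonclassical HLA class I molecule of extravillous cells, was 2.75-fold lower (792 ± 18.0 to 288 ± 21.5 RPKM). ASCL2, a transcription factor of the extravillous lineage, was 2.36-fold lower, and MMP2, a gelatinase, was 2.14-fold lower. ADAM19, HTRA4 and CSH1 were 3.10-fold, 2.64-fold and 3.97-fold lower. TIMP3, an inhibitor of metalloproteinases, and UTRN rose, with log2 fold changes of 0.73 and 1.08. FLT4 was at 9.05 ± 0.293 RPKM with the control shRNA and 7.76 ± 0.657 with the NOTUM shRNA (SD, n = 3; limma adjusted p = 0.0303), and that call ended without control replicate 1 (0.0718), control replicate 2 (0.0778) or NOTUM shRNA replicate 3 (0.132), and with no filter on low values (0.0701). The median log2 fold change of the list was -0.78, and camera with a preset correlation of 0.01 placed it below other genes (adjusted p = 5.68e-22, and adjusted p = 0.107 with an estimated correlation). With median-of-ratios scaling, 38 members were lower and 3 higher. Reads of HLA-G and CSH1 can be shared with near-identical relatives, so their separate levels are uncertain.

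Of 33 measured markers of trophoblast stem cells and cytotrophoblast, the progenitors of the other lineages, 26 rose, 3 fell and 4 did not pass, and the counts adjusted over the list alone were the same. NPPB, which encodes brain natriuretic peptide, was 3.91-fold higher (25.2 ± 0.556 to 98.6 ± 8.35 RPKM, SD, n = 3). The endocytic receptor LRP2 was 3.62-fold higher, PAGE4 3.42-fold and the epithelial adhesion molecule EPCAM 2.88-fold. TEAD4, a transcription factor of the trophoblast progenitor state, was 2.63-fold higher (5.55 ± 0.398 to 14.6 ± 0.754 RPKM) and TP63, a factor of basal epithelial and cytotrophoblast cells, 2.61-fold (1.17 ± 0.142 to 3.04 ± 0.317 RPKM). PEG3 and the integrin ITGA6 rose less, 1.68-fold and 1.47-fold. LIN28B, GATA2 and TFAP2A fell, with log2 fold changes of -0.23, -0.36 and -0.16. The median of the list was 0.58, and camera placed it above other genes (adjusted p = 3.07e-06, and adjusted p = 0.15 with an estimated correlation). With median-of-ratios scaling, 24 members were higher and 5 lower.

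Cell cycle genes moved with the progenitor markers. Of 33 measured genes of mitosis and G2/M, 32 rose and 0 fell, among them MKI67 (1.69-fold, 5.67 ± 0.364 to 9.56 ± 0.245 RPKM, SD, n = 3), MYBL2 (2.31-fold), FOXM1 (2.17-fold) and CDC20 (1.88-fold). The remaining gene was CCNB1, at 73.4 ± 2.61 RPKM with the control shRNA and 70.8 ± 3.71 with the NOTUM shRNA (limma adjusted p = 0.342, and 0.00773 with a negative fold change after median-of-ratios scaling). Of 34 measured genes of DNA replication and G1/S, 27 rose, 1 fell and 6 did not pass, with TYMS, GINS1 and RFC2 1.57-fold, 2.01-fold and 1.65-fold higher. The gene that fell was CCNE1, which encodes cyclin E1 (313 ± 8.48 to 185 ± 13.8 RPKM). Adjusted over the list alone, 32 mitosis genes rose and 0 fell, and 28 replication genes rose and 1 fell. Camera gave adjusted p = 3.37e-08 for the mitosis list and 0.00278 for the replication list (adjusted p = 0.134 and adjusted p = 0.107 with an estimated correlation).

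The measured WNT/beta-catenin target genes rose on balance, at low levels for many members. The list holds 41 genes, with NOTUM left out as the gene targeted. Only 17 of them reached the filter, so the list as a whole was not tested. Of these 17 measured targets, 13 rose, 3 fell and 1 did not pass, and the counts adjusted over the list alone were the same. CCND1, which encodes cyclin D1, was 2.56-fold higher (8.29 ± 0.307 to 21.2 ± 1.27 RPKM, SD, n = 3). GPRC5B and CCDC88C were 3.79-fold and 2.58-fold higher, and AMOTL2 1.74-fold. AMOTL2 is also in the list of HIPPO-YAP targets below. AXIN2, a feedback inhibitor of the pathway, rose from 12.3 ± 0.644 to 15.2 ± 0.318 RPKM, 1.24-fold, and RNF43, a ligase that removes WNT receptors, from 2.09 ± 0.307 to 5.12 ± 0.259 RPKM, 2.45-fold. The log2 fold change of AXIN2 was 0.29 as deposited (limma adjusted p = 0.000935) and 0.18 after median-of-ratios scaling (0.0142). With that scaling, 13 members of the list were higher and 3 lower. EPHB2, EPHB3 and TBX3 fell, with log2 fold changes of -0.57, -0.77 and -0.16. LGR5, NKD1 and LEF1 were among the members below the filter and were not tested, with highest values of 0.034, 0.113 and 0.182 RPKM. The median of the list was 0.65, and camera gave adjusted p = 0.0127 (adjusted p = 0.261 with an estimated correlation). Of 27 measured WNT ligands, receptors and secreted modulators, 16 rose, 6 fell and 5 did not pass, the same adjusted over the list alone. The ligands WNT6 and WNT10A were 2.58-fold and 5.14-fold higher and the receptor FZD5 2.33-fold higher, while the ligand WNT7A, the secreted WNT antagonist SFRP1 and the glypican GPC4 fell, with log2 fold changes of -0.65, -0.94 and -0.95. Camera did not separate this list from other genes (adjusted p = 0.591).

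Of 50 measured markers of syncytiotrophoblast, the fused hormone-producing layer of the placenta, 28 fell, 10 rose and 12 did not pass; adjusted over the list alone, 31 fell and 11 rose. The falls were mostly small. CGA, the alpha subunit of chorionic gonadotropin, was 1.20-fold lower (6577 ± 126 to 5474 ± 266 RPKM, SD, n = 3), SDC1 1.23-fold and the fusogen ERVFRD-1 1.39-fold. Larger falls were those of CSH2 (3.75-fold), TFPI2 (2.20-fold), GCM1, a transcription factor needed for fusion (1.93-fold), and CYP11A1, the first enzyme of steroid synthesis (1.54-fold). PSG9, PSG1 and HSD17B1 rose, with log2 fold changes of 0.52, 0.51 and 0.38. The median of the list was -0.17, and camera placed it below other genes (adjusted p = 5.05e-07, and adjusted p = 0.107 with an estimated correlation). With median-of-ratios scaling, 35 were lower and 7 higher. The CSH and PSG genes, and the CGB genes of the beta subunit of chorionic gonadotropin, are near-identical copies whose reads the authors' counting may split between them. Members of these families are among the 28 falls, which are therefore not all separate. On the log2(RPKM + 1) scale, 8 of the 28 falls reached 1.5-fold. CSH1 is counted in the extravillous list and CSH2 in this one, so their falls are not separate evidence for each lineage.

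**Figure D3:**
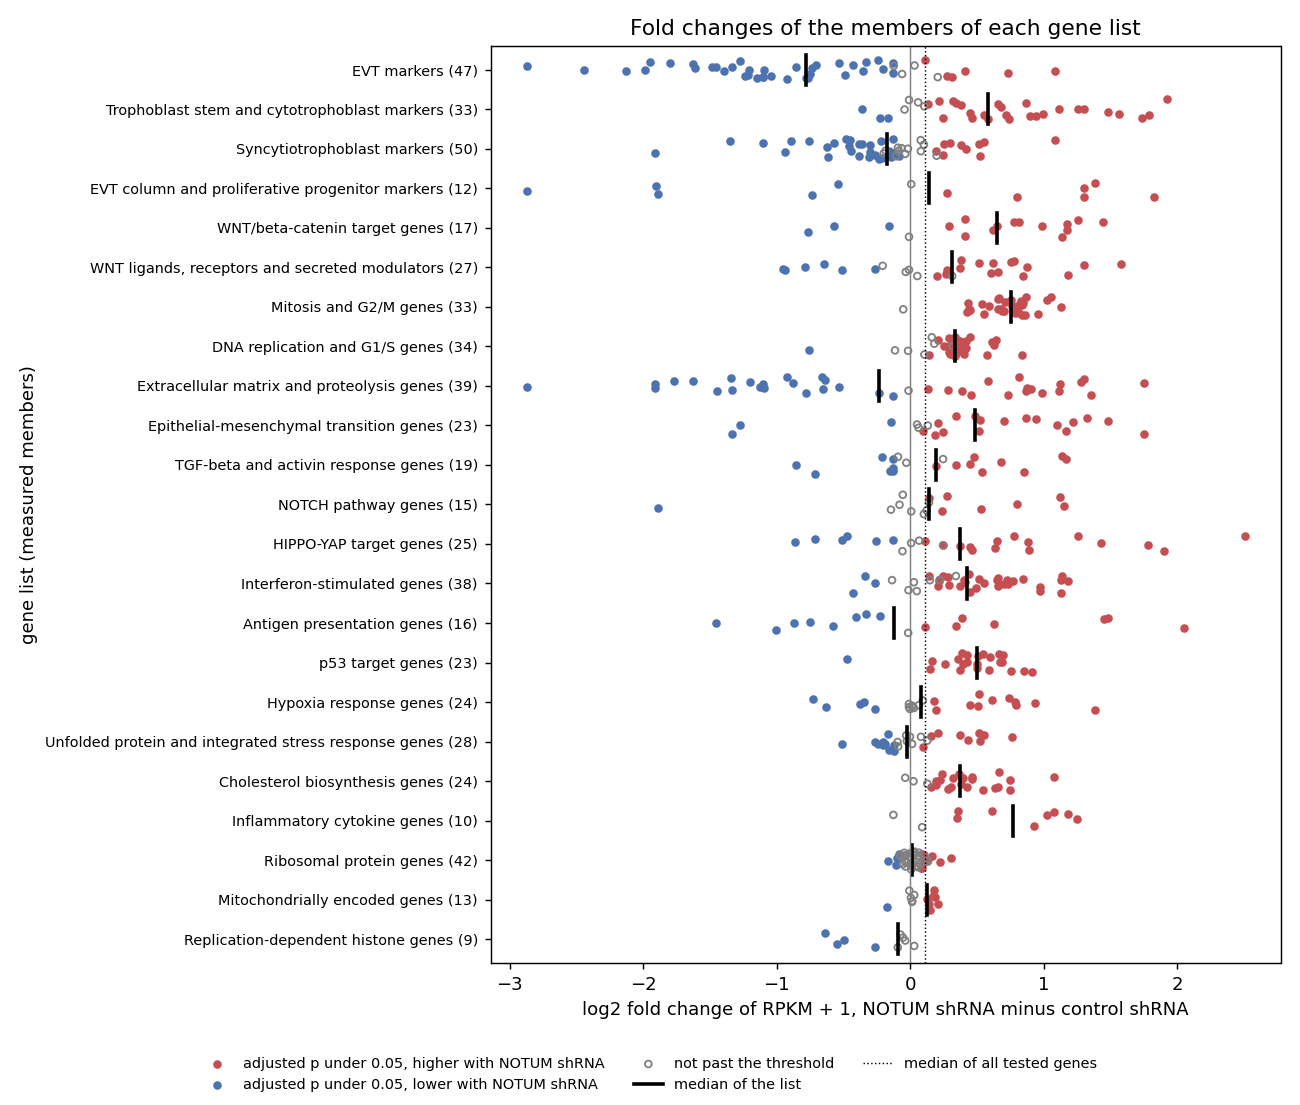
Log2 fold change of RPKM + 1, NOTUM shRNA minus control shRNA, for each measured member of the gene lists with at least 9 measured members, 1 point per gene, filled where the limma adjusted p is under 0.05. Black bars are list medians and the dotted line is the median of all tested genes, 0.11; extravillous markers lie mostly to the left (median -0.78) and stem markers (0.58) and mitosis genes (0.76) to the right.

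Matrix and adhesion genes divided. Of 39 measured genes of the extracellular matrix and its proteolysis, 21 fell, 17 rose and 1 did not pass, the same adjusted over the list alone. The basement membrane proteoglycan HSPG2 was 3.80-fold lower, SPARC 2.54-fold, fibronectin (FN1) 2.53-fold and COL4A1 2.30-fold. The laminin chains LAMB3 and LAMA1 were 3.67-fold and 2.61-fold higher. Camera placed the list below other genes (adjusted p = 0.0014, and adjusted p = 0.167 with an estimated correlation). The list shares members with the extravillous list, among them MMP2, SERPINE2, FN1 and ADAM19, which fell, and TIMP3, which rose. The results of these lists are therefore not separate. Of 23 measured genes of the epithelial-mesenchymal transition list, which holds both epithelial and mesenchymal genes, 17 rose, 3 fell and 3 did not pass, the same adjusted over the list alone. The epithelial genes EPCAM and OCLN were 2.88-fold and 2.69-fold higher, the mesenchymal-associated genes S100A4 and TGFBI were 3.60-fold and 2.67-fold higher, and the transcription factor SNAI1 was 2.51-fold lower. SNAI1 and FN1 are also in the extravillous list and EPCAM in the stem list, so this list is not separate from those either. Camera gave adjusted p = 0.00278 (adjusted p = 0.107 with an estimated correlation).

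Of 12 measured markers of the extravillous column and its proliferative progenitors, 6 rose, 5 fell and 1 did not pass, the same adjusted over the list alone. Some members that fell, SERPINE2 among them, are also in the extravillous list, and some that rose are also in the stem list. The count is therefore not separate from those lists and does not show that progenitor markers fell. TAGLN and the integrin ITGB6 were 3.59-fold and 3.18-fold higher, while NOTCH2 and LRRC32 were 3.96-fold and 3.82-fold lower. The median of this list was 0.14, its mean -0.09 and its camera direction down (adjusted p = 0.486). Of 25 measured HIPPO-YAP targets, 15 rose, 6 fell and 4 did not pass, with 16 and 6 adjusted over the list alone. CYR61, F3 and CRIM1 were 3.50-fold, 3.89-fold and 1.86-fold higher beside AXL. Camera gave adjusted p = 0.11.

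Markers of other cell types were sparse, and some of them moved with the progenitor markers. Of 4 measured markers of villous stromal fibroblasts, COL1A2 rose 3.42-fold (61.7 ± 2.39 to 211 ± 3.14 RPKM, SD, n = 3), COL1A1 rose 1.91-fold and FBLN1 fell by 0.51 on the log2 scale; ACTA2 was at 0.767 ± 0.199 RPKM with the control shRNA and 1.39 ± 0.305 with the NOTUM shRNA (limma adjusted p = 0.0129, and 0.0527 without control replicate 3), and fell below the filter without NOTUM shRNA replicate 2 or 3. Of 4 measured amnion-like markers, KRT17, ITGB6 and BAMBI rose 4.25-fold, 3.18-fold and 2.56-fold and 1 did not pass. Of 4 measured endothelial markers, ESAM fell by 0.64 on the log2 scale and 2 did not pass; PECAM1, at 4.60 ± 0.283 and 3.41 ± 0.765 RPKM, passed with all 6 libraries (limma adjusted p = 0.0177) and not without control replicate 2 (0.0539), NOTUM shRNA replicate 2 (0.0738) or NOTUM shRNA replicate 3 (0.0681), nor with no filter on low values (0.065). Of 2 measured macrophage and leukocyte markers, CD68 fell by 0.72 on the log2 scale and 1 did not pass. Adjusted over the list alone, 2 leukocyte markers were lower, as they were over all genes after median-of-ratios scaling or without NOTUM shRNA replicate 1; the other 3 lists kept their counts when adjusted over the list alone. None of the decidual stromal markers reached the filter, so 0 were tested.

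The counts of ribosomal protein and mitochondrially encoded genes in each direction depended on the scaling. Of 42 measured ribosomal protein genes, 9 rose, 4 fell and 29 did not pass, against 2 higher and 22 lower after median-of-ratios scaling; adjusted over the list alone, 3 rose and 1 fell. RPS19 rose 1.24-fold and RPS6 fell by 0.16 on the log2 scale, both under either scaling. Their count of 13 members past the threshold became 7 without control replicate 2, 6 without NOTUM shRNA replicate 2 and 6 without NOTUM shRNA replicate 3. The ribosomal list had a median of 0.02 and a mean of 0.03, and its camera direction was down (adjusted p = 0.367). Of 13 mitochondrially encoded genes, 7 rose and 1, MT-ND1, fell, against 2 higher and 6 lower after scaling, with the same 7 and 1 adjusted over the list alone (camera adjusted p = 0.486). Of 9 measured replication-dependent histone genes, which lack poly(A) tails in their main form, 4 fell and 0 rose, the same adjusted over the list alone (camera adjusted p = 0.00278, and adjusted p = 0.107 with an estimated correlation). HIST1H2BC, HIST1H2AC, HIST2H2BE and HIST1H2BK fell by 0.64, 0.55, 0.49 and 0.26 on the log2 scale.

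The authors' deposited table gave 542 transcripts with an FDR p under 0.05, 179 higher and 363 lower with the NOTUM shRNA. In the authors' deposited table these transcripts belonged to 419 genes, of which 406 passed here in the same direction and 5 in another or a mixed direction. The log2 of the fold in the authors' deposited table lay 0.115 below the log2 ratio of mean RPKM (a difference of -0.115, interquartile range 0.0038, over 10486 transcripts), the size of the shift between the 2 scalings here. For NOTUM, the authors' deposited table gives 1 transcript a signed fold of -29.3.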

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

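Testing each transcript on its own, and median-of-ratios scaling joined with a fold of at least 1.5, were chosen after the data were seen; the other settings were planned. Median-of-ratios scaling raised the genes lower with the NOTUM shRNA to 3013 (3275 higher), as follows from subtracting a shift of 0.115. A fold of at least 1.5 on the log2(RPKM + 1) scale left 1666 genes (1215 higher, 451 lower), 16 stem markers higher and 8 syncytiotrophoblast markers lower; with median-of-ratios scaling as well, it left 1537 (920 higher, 617 lower). A mean of at least 5 RPKM left 6 WNT targets higher, since fewer members were tested. With single transcripts tested, genes past the threshold were 4082 and genes higher with NOTUM shRNA 2796; the cause was not tested. Leaving out 1 library at a time gave 5735 to 6448 genes past the threshold (genes higher with NOTUM shRNA 4117 to 4618, genes lower with NOTUM shRNA 1618 to 1837), a NOTUM log2 fold change of -4.66 to -4.46, 34 to 37 extravillous markers lower, 25 to 26 stem markers higher, 24 to 29 syncytiotrophoblast markers lower and 13 to 14 WNT targets higher. Same-numbered libraries did not deviate together (correlations across genes of -0.14, 0.05 and -0.11), so the numbers do not pair them; with the replicate block, 6217 genes passed (4489 higher, 1728 lower). Of 156 named genes, 142 could be run under all 14 alternatives, and 104 of these 142 kept their direction and call; the genes outside the 142 fell below a filter under at least 1. Of the 156, 41 crossed the threshold somewhere without changing direction, and 1, MX1, which passed under none, changed sign (-0.0848 with median-of-ratios scaling; -0.000268 to 0.0698 with 1 library left out). DESeq2's and voom's count tests and unique-read counts were not run for want of counts. The planned settings of library totals and of a fit on normalized values are the main fit itself, so they add no check. At 23.5 to 33.5 M, a difference of under 0.0298 RPKM is less than 1 read on a 1 kb transcript.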

Other observations

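Genes of the p53 response and of cholesterol synthesis were also higher with the NOTUM shRNA. Of 23 measured p53 targets, 22 rose and 1 fell, the same adjusted over the list alone. CDKN1A, which encodes the cell cycle inhibitor p21, was 1.62-fold higher (87.8 ± 5.18 to 142 ± 3.11 RPKM, SD, n = 3), and TNFRSF10B, PLK3 and DDB2 were 1.61-fold, 1.93-fold and 2.05-fold higher, while GDF15 fell by 0.47 on the log2 scale. Camera gave adjusted p = 3.13e-05 (adjusted p = 0.107 with an estimated correlation). Of 24 measured genes of cholesterol synthesis, 21 rose and 0 fell (22 and 0 adjusted over the list alone), with FDPS, EBP, CYP51A1 and ACAT2 between 1.56-fold and 1.71-fold higher; camera gave adjusted p = 3.15e-05 (adjusted p = 0.107 with an estimated correlation). After median-of-ratios scaling the counts were 19 higher and 1 lower for p53 targets, and 16 higher and 1 lower for cholesterol synthesis.

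Of 38 measured interferon-stimulated genes, 28 rose, 3 fell and 7 did not pass, the same adjusted over the list alone. IFI27, IFI6, IFITM3 and OAS3 were 2.20-fold, 1.63-fold, 1.71-fold and 2.34-fold higher. STAT2, EPSTI1 and IFIT5 fell, with log2 fold changes of -0.34, -0.43 and -0.26; the IFIT5 call (limma adjusted p = 0.024) ended with no filter on low values (0.0592) and without control replicate 1 (0.0817), NOTUM shRNA replicate 2 (0.0868) or NOTUM shRNA replicate 3 (0.0812). MX1 was at 41.9 ± 2.24 and 42.7 ± 1.46 RPKM (limma adjusted p = 0.652). Control replicate 1, the library from another lane, was the highest of the controls in 29 of the 38 genes; IFIT2 was at 8.46 RPKM there against 4.22 and 4.29 in control replicates 2 and 3. IFIT2 and IFIT3 did not pass with all libraries (limma adjusted p = 0.205 and 0.192) and passed as higher without control replicate 1 (0.000189 and 0.00105). The number of members past the threshold was 31 with all libraries and 31 without control replicate 1, though not the same members. After median-of-ratios scaling, 23 members were higher and 4 lower. Camera gave adjusted p = 0.00116 (adjusted p = 0.529 with an estimated correlation). Of 10 measured inflammatory cytokine genes, 8 rose and 0 fell, the same adjusted over the list alone, among them IL32 (2.38-fold, 152 ± 8.01 to 361 ± 5.05 RPKM, SD, n = 3), TNF, IL6 and CCL5 (3.26-fold, 2.99-fold and 2.15-fold, at low levels); camera gave adjusted p = 0.00447 (adjusted p = 0.167 with an estimated correlation). Antigen presentation genes divided, with 7 higher, 8 lower and 1 not passing of 16 measured, the same adjusted over the list alone: HLA-A and HLA-B rose while HLA-G and the peptide transporter TAP2 fell (log2 fold changes of 2.05, 1.45 and -1.46 for the HLA genes, whose reads can be shared, and 2.05-fold lower for TAP2). The median of that list was -0.12 and its mean 0.05 (camera adjusted p = 0.124).

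The remaining lists showed no common direction by camera. Of 24 measured hypoxia genes, 11 rose and 5 fell (adjusted p = 0.716), with EGLN3, SLC2A3 and LDHA higher and PFKFB4 lower; after median-of-ratios scaling 9 were higher and 7 lower. Of 28 genes of the unfolded protein and integrated stress responses, 9 rose and 11 fell (adjusted p = 0.146; 10 and 11 adjusted over the list alone), with PSAT1, ATF3, VLDLR and CHAC1 higher and CRELD2 and PDIA4 lower (log2 fold changes of -0.51 and -0.24). After median-of-ratios scaling 6 were higher and 15 lower; the list's median was -0.03 and its mean 0.05. Of 15 NOTCH pathway genes, 7 rose and 1 fell (adjusted p = 0.599), with NOTCH3, NOTCH1 and HES4 higher and NOTCH2 lower; after median-of-ratios scaling 4 were higher and 3 lower, and without NOTUM shRNA replicate 2 the 8 genes past the threshold became 5. Of 19 TGF-beta and activin response genes, 9 rose and 7 fell (adjusted p = 0.793; 10 and 8 adjusted over the list alone), with BAMBI, TGFBI and COL1A1 higher and FSTL3 lower, and 8 higher and 8 lower after median-of-ratios scaling; its median was 0.19 and its mean 0.19, with a camera direction of down. The hypoxia and NOTCH counts were the same adjusted over the list alone.

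For the patterns below, the tests of 1 scale factor, of shared HLA reads, of RNA from fibroblasts or leukocytes, and of replicate 1 were chosen after the results were seen; those of depth, of gene length and GC content, and of the other splits were chosen before. In the values as deposited, more genes rose than fell. The log2 ratio lay above 0 in 71.9% of genes of 1 to 5 RPKM and in 51.4% of genes of 100 to 1000 RPKM. The median log2 ratio of the first range exceeded that of the second by 0.224 (95% bootstrap interval over genes 0.195 to 0.254, and 0.18 to 0.276 over the 9 pairs of libraries). A single scale factor shifts every gene alike and so does not give this difference, although median-of-ratios scaling evens the split of calls. Deeper NOTUM shRNA libraries are argued against, since the deepest against the shallowest library within a group differed by 0.0467 (0.0325 to 0.0586) in the controls, at depths 1.18-fold apart, and 0.0177 (0.00658 to 0.0299) in the NOTUM shRNA group, at 1.22-fold, the same ratio as between the group means. Adjusting for transcript length and GC content, known for 90.8% of the genes, left the difference at 0.244 (0.215 to 0.272). The difference between the ranges is the same under any shared shift, so it cannot tell a rise of low genes from a fall of high genes. In the authors' deposited table, whose log2 folds lie 0.115 lower, 179 transcripts were higher and 363 lower. A wider set of genes transcribed at low levels with less NOTUM stays open as a hypothesis, as does an off-target effect of the shRNA. The real grouping gave 6666 genes past the threshold with limma and 1 of the 10 possible splits reached that number, the real one. The highest other gave 0 (at most 250 at an unadjusted p under 0.05), and 10 splits are too few for a share under 0.05. Each other split mixes both groups on each side, so the group difference adds to its spread. The 0 therefore does not measure false calls.

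HLA-A, HLA-B, CD74 and COL1A2, genes abundant in stromal or immune cells, rose together: HLA-A from 1.02 ± 0.0662 to 7.37 ± 0.226 RPKM, and CD74 from 1.60 ± 0.304 to 6.23 ± 0.55 RPKM (SD, n = 3). A fixed share of HLA-G reads counted for HLA-A and HLA-B would have made them fall with it, but the smaller rise, that of HLA-B, was 1.45 on the log2 scale. How reads that match several genes were counted is not given, and this rise is part of the pattern itself. Other forms of read sharing therefore stay open. RNA from fibroblasts would bring COL3A1, DCN and LUM, whose joint rise was at most 0.354% of that of COL1A2 in any NOTUM shRNA library. Their control means were 0.223, 0 and 0.0367 RPKM and their NOTUM shRNA means 0.368, 0.0268 and 0.225. DCN is listed at 0 in 5 libraries, which can be a failed estimate. COL1A1, well above the floor and also abundant in fibroblasts, rose by 3.85% to 5.22% of the rise of COL1A2. These small rises speak only against fibroblasts as the main source of the COL1A2 rise, if the estimates hold. Some RNA from fibroblasts stays open. RNA from leukocytes stays open: PTPRC and HLA-DRA together rose by at most 0.0709% of the rise of CD74, but HLA-DRA is listed at 0 in all 6 libraries and VIM, widely expressed in cultured cells, at no more than 0.0319 RPKM, so a 0 can be a failed estimate, and the leukocyte genes LAPTM5 and CD14, below the filter, had means of 0.31 and 0.0452 RPKM with the control shRNA and 0.955 and 0.288 with the NOTUM shRNA. Expression of these genes by the trophoblast cells themselves is a hypothesis that stays open too, and other cell types were not tested.

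NOTUM shRNA replicate 1 lay nearest to the controls in 112 of 132 genes that fell and 150 of 237 that rose. These genes changed by at least 1 on the log2 scale at a mean of at least 5 RPKM. An even share among the libraries would be 33.3%, but that is not a chance level. Genes move together, so 1 small difference of 1 library can recur in many of them. Cells lacking the shRNA in that library stay open as an explanation, although cells were selected with puromycin, per the series design text. NOTUM lay 1.23% of the way to the controls and the genes that fell a median of 6.44%. The 95% bootstrap interval of 5.39 to 7.62 is over genes within that 1 library, so it does not measure the spread between transductions. NOTUM is secreted, so a few such cells could act on the others, and these positions cannot decide. A scale factor of replicate 1 would bring it nearer in 1 direction only, and the lower share of the 2 directions was 63.3%. A slower or less complete response in that transduction may be at work. NOTUM stood at 5.02% of the control mean in replicate 1, against 3.81% and 3.86% in replicates 2 and 3. Whether that difference matters was not tested, nor was any other biological explanation, and the labels give the replicates no other difference.

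No change in a transcript's share of its gene's RPKM was called: limma passed 0 of 15834 transcripts in 6671 genes (smallest adjusted p = 0.0924), with 1424 (8.99%) at an unadjusted p under 0.05. On simulated shares of these transcripts, the same test recovered 55% of 100 changes of 20 points and 85% of 100 changes of 40 points.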
